A study of Mus musculus with 7 samples.

How the data were processed

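Sorted live CD45+ cells from B78 flank tumours were profiled in 7 libraries, 1 for each of Sham, BT, ICI, BT+ICI, 2Gy+ICI, 8Gy+ICI and 20Gy+ICI. Group and external beam dose were taken from the sample labels. The treatment labels of BT and BT+ICI name brachytherapy without a dose. The series names C57BL/6 and FVBn mice as hosts, and which library came from which strain is not given in the sources used here. Tumours were dissociated, red cells were lysed, and cells were loaded on the 10x Chromium 3′ v3 system. Per the file headers the deposited matrices hold counts, that is, unnormalized UMI counts per gene and cell barcode from Cell Ranger 6.1.2, and the genome build is mm10 per the labels. The cell calling settings and the gene annotation release are not given in the sources used here. Each matrix held 32285 genes.

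Cells with at least 300 genes and at most 10% mitochondrial counts were kept. The mitochondrial limit removed 5.99 to 14.7% of barcodes. Doublets were scored per library by the share of simulated doublets (2 per cell) among 50 neighbours, and the highest-scoring cells were removed at 0.8% per 1000 cells, which took out 5.90 to 8.14% of cells. In all, 59565 of 72637 barcodes were kept, 79.1 to 87.8% per library. Cells of all libraries were clustered together on log-normalized counts, 2000 variable genes and 30 principal components without correction between libraries, with a graph of 20 shared neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). A cluster took a class when at least 3 markers of that class were detected in it above other clusters and no other class had more markers among its 10 leading genes. This left 6 of 26 clusters without a class. Of these, 3 had few UMIs per cell (median 0.127 to 0.233 of that of the library), a threshold set after the data were examined, and the others carried markers of more than 1 class or few of any. They were not split further.

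Shares were computed among T cells, among myeloid cells, among named leukocytes and among all cells kept, with exact Clopper-Pearson intervals, and ratios of shares with ranges from 10000 draws. For expression, counts were summed over the cells of a class with at least 100 cells in each library compared, scaled to CPM of the class total, and compared as the log2 ratio of CPM plus 5. Exact Poisson intervals were computed for each sum and exact binomial intervals for each ratio of counts. With 1 library per group no test, p-value or count of changed genes is given. The comparisons were BT with Sham, ICI with Sham, BT+ICI with ICI, each external beam library with ICI, and BT+ICI with each external beam library. BT+ICI against BT, 20Gy+ICI against 2Gy+ICI, and the difference between brachytherapy with and without ICI were added by the design. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Figures used matplotlib 3.10.9.

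Genes were chosen for naming by a rule fixed before the data were opened. In CD8 T cells and in monocytes with macrophages, among genes with at least 100 UMIs and 20 CPM in 1 library, the 5 largest and the 5 smallest log2 ratios were taken. Where 1 library was compared with 3, genes had to have the same sign against each and were ranked by the ratio nearest 0. Left out were mitochondrial, ribosomal protein, antibody, T cell receptor segment, hemoglobin, X-inactivation and Y-linked genes, predicted genes, and genes under 0.1 of their level in the class where they are highest. Members of the gene lists, also fixed in advance, were named in addition. There were 29 lists (p53 response, DNA repair and damage sensing, type I interferon response, cGAS-STING and type I interferon genes, interferon gamma response, MHC class I presentation, MHC class II presentation, cytotoxic effector, inhibitory receptor and exhaustion, naive and memory T, regulatory T activation, cell cycle S, cell cycle G2/M, inflammatory macrophage, alternative macrophage, lipid-associated macrophage, complement and tissue-resident macrophage, hypoxia and glycolysis, chemokines attracting T cells, checkpoint ligands and co-stimulation, TGF-beta and matrix remodelling, NF-kB inflammation and neutrophil recruitment, dissociation and heat shock stress, oxidative phosphorylation, mitochondrially encoded, red blood cell free RNA, neutrophil free RNA, melanoma free RNA and fibroblast free RNA). List members with at least 20 UMIs were used, and each median was ranked among 10000 random lists matched in 20 expression bins. T cell lists were read in T cells and macrophage lists in myeloid cells, apart from T cell lists in DC and macrophage lists in regulatory T cells, which are given beside other lists there. Other classes were read through lists only, where both libraries held at least 200 cells.

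The size of 0.2 log2 below which no direction is given, the restriction of lists to their class, and which value stands for each entry of the design were set after the data were examined. Under these choices 31 of 7571 alternative values were counted as sign changes, and without the size limit and the restriction 54 of 9230. A sign change was counted only where the counting range of the reported value did not span both signs. The totals of 7571 and 9230 also hold values that could not be counted. Neither count therefore gives the share of all alternative values that differed in sign. Alternatives fixed in advance were 500 genes, 5 or 20% mitochondrial counts, no doublet removal, resolution 0.5 or 2, components centred per library, gates on single cells, TMM totals (edgeR 4.0.16 in R 4.3.3, used for scaling factors only, 0.930 to 1.09), totals without mitochondrial, ribosomal protein and receptor genes, pseudocounts of 1 or 20, a UMI minimum 5 times as high, equal cluster weights and cells thinned to 2000 UMIs. Others, chosen after seeing the data, gave low-UMI clusters a class, left out the naive-type T and B clusters, corrected for transcript length in 20 bins, or left out the CD8 cluster with Ifit1 and Ifit3. Transcript length was first taken over all transcripts and then over protein-coding ones after its result was seen, with the same outcome.

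The gene comparison was tested on simulated data made from BT and Sham, with 200 genes changed. Both simulated libraries were drawn as Poisson counts from 1 pooled profile, the model that the intervals assume. The simulation therefore checks the computation under counting error and holds no spread between animals or handling. In CD8 T cells 98.0% of genes raised 4-fold and 94.0% of those raised 2-fold lay inside their intervals, with median log2 ratios of 1.86 and 0.94. In monocytes and macrophages these were 96.0 and 98.0%, with 1.67 and 0.82. All of the 10 highest and 10 lowest genes were changed ones. Of 200 lists without change, 13 fell outside the central 95% of random lists, and a list shifted 2-fold came out at 0.90 and 0.85. The ratio of CPM plus 5 understates the change of genes at low CPM.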

Results

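The series asks how an uneven radiation dose inside a tumour shapes the response to immune checkpoint blockade. B78 melanomas were grown under the flank skin of mice, and live CD45+ cells were sorted from the tumours on day 10 and profiled by 10x Chromium 3′ RNA sequencing. The 7 groups were a mock-treated control (Sham), brachytherapy with an iridium source that delivered 2 Gy at the near edge of the tumour (BT), antibodies against CTLA-4 and PD-L1 (ICI), brachytherapy with these antibodies (BT+ICI), and external beam radiation of 2, 8 or 20 Gy with them (2Gy+ICI, 8Gy+ICI and 20Gy+ICI). In that order the libraries held 8760, 10283, 11485, 11369, 10449, 11654 and 8637 cell barcodes, with medians of 9093.5, 6903, 5302, 6747, 4096, 4455 and 8161 UMIs per barcode. After filtering, 7692, 8777, 9309, 9347, 8273, 9218 and 6949 cells were kept, with medians of 9122, 6958, 5621, 7052, 4821, 5224 and 8733 UMIs per cell.

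Each group had 1 library, so the spread between animals is unknown and no difference was tested. Intervals cover counting error only, and "higher" and "lower" describe these libraries. Shares are given with exact 95% intervals. Expression was summed over the cells of a class and is given as CPM (counts scaled to the class total), with the log2 ratio of CPM plus 5 between libraries. List percentiles rank a list's median log2 ratio among those of 10000 random lists matched for expression in the same libraries.

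T cells and macrophages made up most of the named leukocytes. T cells were 28.5, 36.3, 47.7, 56.0, 45.2, 54.1 and 62.6% of named leukocytes in Sham, BT, ICI, BT+ICI, 2Gy+ICI, 8Gy+ICI and 20Gy+ICI, and NK cells or type 1 innate lymphoid cells were 2.44, 2.80, 2.55, 2.81, 5.15, 5.24 and 3.39%. Macrophages were 83.8, 82.3, 79.6, 67.1, 62.9, 59.6 and 62.2% of myeloid cells, monocytes 7.81, 8.20, 10.5, 12.2, 22.05, 25.9 and 23.8%, dendritic cells (DC) 7.13, 8.73, 7.46, 5.19, 10.1, 7.64 and 6.77% and neutrophils 1.28, 0.807, 2.42, 15.6, 4.93, 6.88 and 7.26%. Among T cells, the CD8 share was 21.8, 38.4, 16.1, 65.9, 35.1, 67.3 and 80.9% and the regulatory share 39.6, 42.1, 31.1, 4.67, 28.9, 6.90 and 2.67%. CD4 conventional T cells were 31.2, 16.3, 30.1, 28.3, 31.3, 23.7 and 15.1%.

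**Figure D1:**
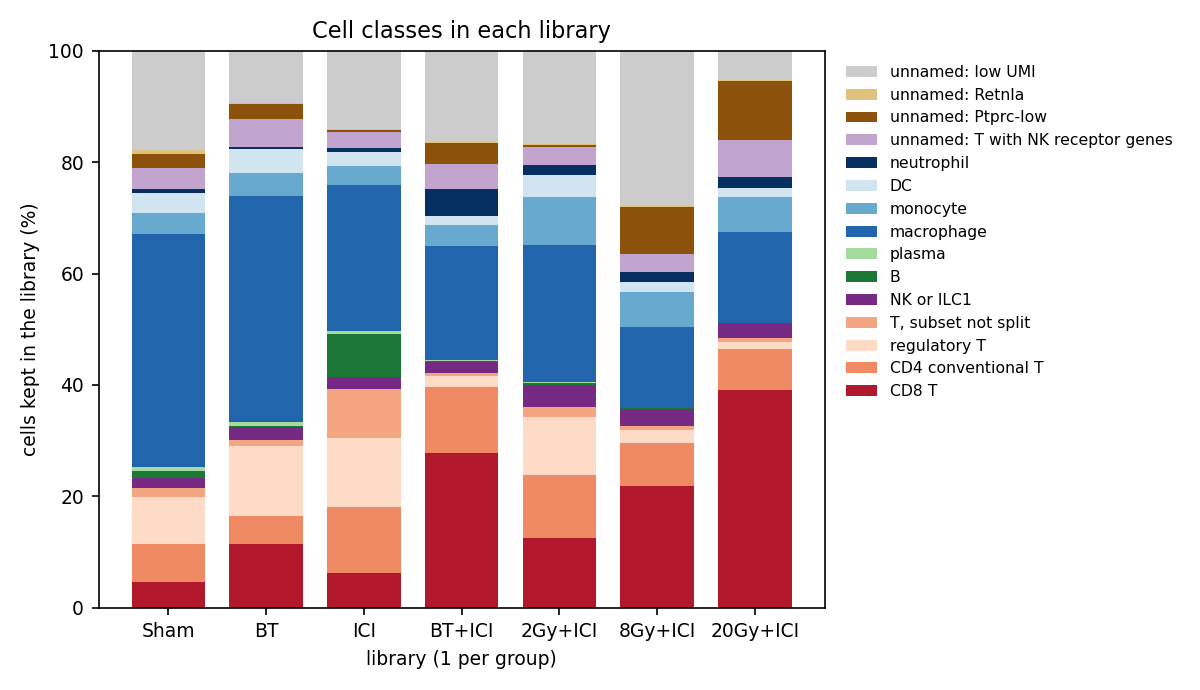
Share of each named class and of the unnamed clusters among the cells kept, per library. Each bar is 1 library.

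Clusters outside these classes differed between libraries too. Cells with Trdc, Klra7 and other NK receptor genes were 3.87, 4.97, 2.79, 4.47, 3.18, 3.40 and 6.71% of cells kept, in the same order of libraries. A cluster with Apod, Mgp and Sox10 and little Ptprc, the gene of CD45, was 2.41, 2.71, 0.483, 3.90, 0.326, 8.42 and 10.6%, although the cells had been sorted for CD45. Cells with Retnla and Lyve1 were 0.741, 0.285, 0.0859, 0.139, 0.133, 0.0542 and 0.201%. Clusters with few UMIs per cell, left without a class by a threshold set after the data were examined, were 17.8, 9.32, 14.1, 16.3, 16.8, 27.9 and 5.19%. They are outside every share and sum given for a named class.

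To ask what brachytherapy did without checkpoint antibodies, BT was compared with Sham. Interferon-stimulated genes were higher in BT in CD8 T cells and in monocytes and macrophages. CD8 T cells also formed a larger part of the T cells, while the regulatory share was similar. Proliferation genes were lower in the CD8 T cells of BT, and the chemokine gene Cxcl9 was lower in its monocytes and macrophages. CD8 T cells were 38.4% (95% interval 36.5 to 40.3) of T cells in BT against 21.8% (95% interval 19.8 to 23.9) in Sham. Regulatory T cells were 42.1% against 39.6%. The ratio of CD8 T to regulatory T cells was 0.913 (95% interval 0.840 to 0.993) in BT and 0.551 (95% interval 0.484 to 0.625) in Sham. CD4 conventional T cells were 16.3% against 31.2%.

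In CD8 T cells of BT against Sham, 29 of 29 measured members of the type I interferon response list were higher, with a median log2 ratio of 2.03 (counting range 1.86 to 2.12, percentile 100). The 5 genes with the largest ratios were all induced by interferon. They were Ifit3b (109 CPM against 9.92 CPM, log2 ratio 2.94), Ifit3 (490.1 against 64.3, 2.84), Isg15 (1251 against 214, 2.52), Usp18 (156 against 23.9, 2.47) and Ifit1 (409 against 69.8, 2.47). Irf7, the transcription factor that amplifies this response, was at 291 CPM in BT and 54.1 CPM in Sham. Of the interferon gamma list, 21 of 23 measured members were higher (median 1.005). The granzyme gene Gzmb was higher (1823 against 686 CPM), while Prf1 (221 against 424) and Ifng (339 against 549.8) were lower, and the cytotoxic list as a whole was near 0 (median 0.09). The largest negative ratios were those of Nrn1 (37.8 against 241, -2.52), Nrgn (22.1 against 124, -2.25), Hist1h1a (11.9 against 41.4, -1.45), C1qtnf6 (5.97 against 24.98, -1.45) and Hist1h2bj (23.5 against 70.1, -1.40). Of the S phase list, 23 of 24 members were lower (median -0.63), as were 26 of 26 of the G2/M list (median -0.42). DNA repair genes had a median of -0.36, and mitochondrially encoded genes one of -0.42.

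The interferon genes of CD8 T cells were gathered in 1 cluster but not confined to it. The cluster with Ifit1 and Ifit3 held 30.2% of CD8 T cells in BT and 6.39% in Sham. With this cluster left out the type I interferon median was 1.11, and with all CD8 clusters given the same weight it was 0.76. Equal weights also gave 0.34 for the interferon gamma list, -0.10 for S phase, -0.04 for DNA repair and, in the other direction, 0.26 for G2/M. Cycling cells were 7.70% of CD8 T cells in BT and 17.2% in Sham.

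**Figure D2:**
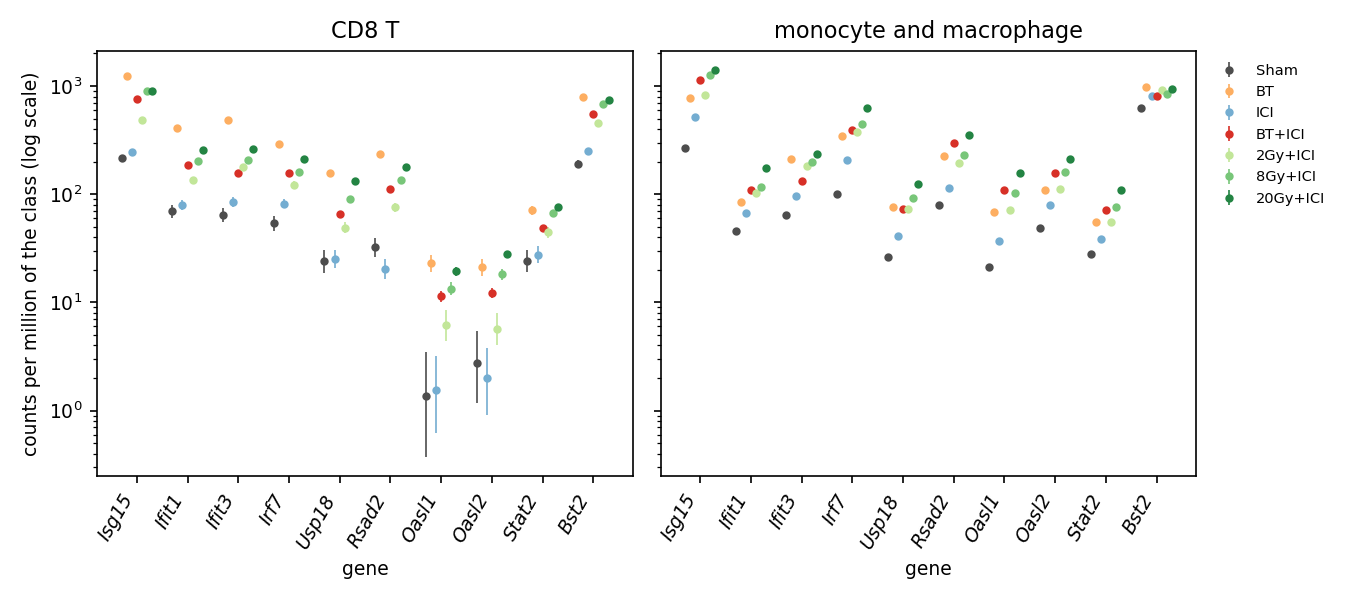
Expression of 10 interferon-stimulated genes in CD8 T cells and in monocytes and macrophages of each library, on a log axis. Bars are 95% counting intervals.

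Monocytes and macrophages of BT had higher type I interferon genes as well. Of the type I interferon list, 30 of 30 members were higher than in Sham (median 1.14, counting range 1.10 to 1.19). The largest ratios were those of Lipg (24.3 CPM against 1.80 CPM, log2 ratio 2.11), Ms4a4c (475 against 132, 1.81), Ifi205 (93.4 against 23.4, 1.79), Ifit1bl1 (22.02 against 3.17, 1.73) and Irf7 (345 against 101, 1.72). The lowest were those of Mgl2 (36.7 against 104, -1.38), Klrb1b (26.7 against 55.3, -0.93), Lilra5 (32.2 against 60.4, -0.81), Tnfsf13b (62.5 against 112, -0.79) and Cxcl9 (857 against 1427, -0.73). MHC class II genes were lower (median -0.43), among them Cd74 (12454 against 19612 CPM) and H2-Aa (4406 against 6478). NF-kB genes were higher in 18 of 19 cases (median 0.35), with Cxcl2 at 1646 against 885 CPM. The complement and tissue-resident list (0.38), the inflammatory list (0.31) and the alternative list (0.29) were higher as well, and the hypoxia list was lower (-0.23). Macrophages with Arg1 and Ly6i were 36.9% of macrophages in BT and 16.5% in Sham, and those with Fcrls and Apoe 38.4% and 44.8%.

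Checkpoint antibodies alone were examined by comparing ICI with Sham. The balance of CD8 T to regulatory T cells was close to that of Sham. The ICI library differed instead in a large set of naive-type T and B cells and in single genes such as Gzma in CD8 T cells. It also differed in interferon gamma and hypoxia genes in monocytes and macrophages. There were 0.517 (95% interval 0.467 to 0.569) CD8 T cells per regulatory T cell, and the log2 ratio to Sham was -0.09 (-0.33 to 0.14). Cells gated one by one on marker genes gave 0.69 instead. T cells with Lef1 and Ccr7 were 8.20% of cells kept in ICI and 0.988% in Sham, and B cells 7.61% and 1.31%.

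In CD8 T cells of ICI against Sham the highest ratios were those of Itgb7 (139 CPM against 38.0 CPM, log2 ratio 1.75), Rasgrp2 (59.4 against 17.1, 1.54), Gpr18 (58.3 against 18.1, 1.45), Klrg1 (31.5 against 9.24, 1.36) and Plac8 (272 against 106, 1.32). Gzma was at 1091 CPM in ICI and 163 CPM in Sham, and Gzmb at 1603 and 686, while the median of the cytotoxic list was 0.07. Members of the naive and memory list were higher in 18 of 22 cases (median 0.47, and 0.81 with cells thinned to 2000 UMIs), with Klf2 at 411 against 112 and Tcf7 at 39.9 against 13.001 CPM. The hypoxia and glycolysis list was higher in 18 of 21 cases (median 0.61). Of the 5 lowest genes 4 encode histones, whose mRNAs largely lack poly(A) tails. They were Hist1h4d (60.1 against 311, -2.28), Hist1h2bj (11.97 against 70.1, -2.15), Hist1h3e (14.6 against 68.1, -1.90) and Hist1h2ab (29.9 against 112, -1.75), and the other gene was Nrgn (32.1 against 124, -1.80). Xcl1, which encodes a chemokine for DC, was at 50.8 against 425 CPM. The type I interferon list was close to Sham (median 0.19), and all 13 mitochondrially encoded genes were lower (median -0.51). MHC class I (0.34), interferon gamma (0.27) and regulatory activation genes (0.31) were higher.

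Macrophages and monocytes of ICI showed more interferon gamma genes than those of Sham, with 26 of 27 members higher (median 0.55, counting range 0.51 to 0.61). Cxcl9 was at 1893 against 1427 CPM, Cd274, the gene of PD-L1, at 144 against 79.9, and Nos2 at 40.9 against 14.2. MHC class II genes were higher (median 0.35), with Cd74 at 26820.0 against 19612 CPM, and so were MHC class I genes (0.48), type I interferon genes (0.48) and the inflammatory list (0.50). The highest single ratios were those of Ly6i (117 against 21.4, 2.21), Ass1 (409 against 103, 1.94), Inhba (92.0 against 24.2, 1.73), Arg1 (436 against 130.3, 1.70) and Saa3 (22.3 against 4.10, 1.59). Macrophages with Arg1 and Ly6i, for which some of these genes are markers, were 31.2% of macrophages in ICI and 16.5% in Sham. The lowest ratios were those of Hist1h4d (25.7 against 117, -1.99), AY036118 (79.6 against 246, -1.57), Hist1h2ap (52.0 against 147, -1.42), Hist1h2ae (60.8 against 167, -1.38) and Hist1h2ab (12.01 against 38.7, -1.36). The hypoxia and glycolysis list was higher in 20 of 23 cases (median 0.31). Mitochondrially encoded genes were lower (median -0.61), as were nuclear genes of oxidative phosphorylation (-0.36). The G2/M list was lower (-0.48) but at -0.01 with equal cluster weights.

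The title of the series links an uneven dose to the response to checkpoint antibodies, and brachytherapy added to them was examined by comparing BT+ICI with ICI. CD8 T cells far outnumbered regulatory T cells in BT+ICI, whereas regulatory T cells were the larger class in ICI. The monocytes and macrophages of BT+ICI carried more Arg1, Nos2, Cxcl2 and PD-L2 transcripts and fewer C1qa and Fcrls transcripts. Neutrophils were a larger part of the myeloid cells, and interferon-stimulated genes were higher in CD8 T cells and in monocytes and macrophages. There were 2592 CD8 T and 184 regulatory T cells in BT+ICI, a ratio of 14.1 (95% interval 12.2 to 16.5), against 589 and 1140 in ICI. The log2 ratio between the libraries was 4.77 (4.52 to 5.04). CD8 T cells were 65.9% (95% interval 64.3 to 67.3) of T cells against 16.1% (95% interval 14.9 to 17.3), and regulatory T cells 4.67% against 31.1%. Neutrophils were 15.6% of myeloid cells against 2.42%, and macrophages 67.1% against 79.6%.

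**Figure D3:**
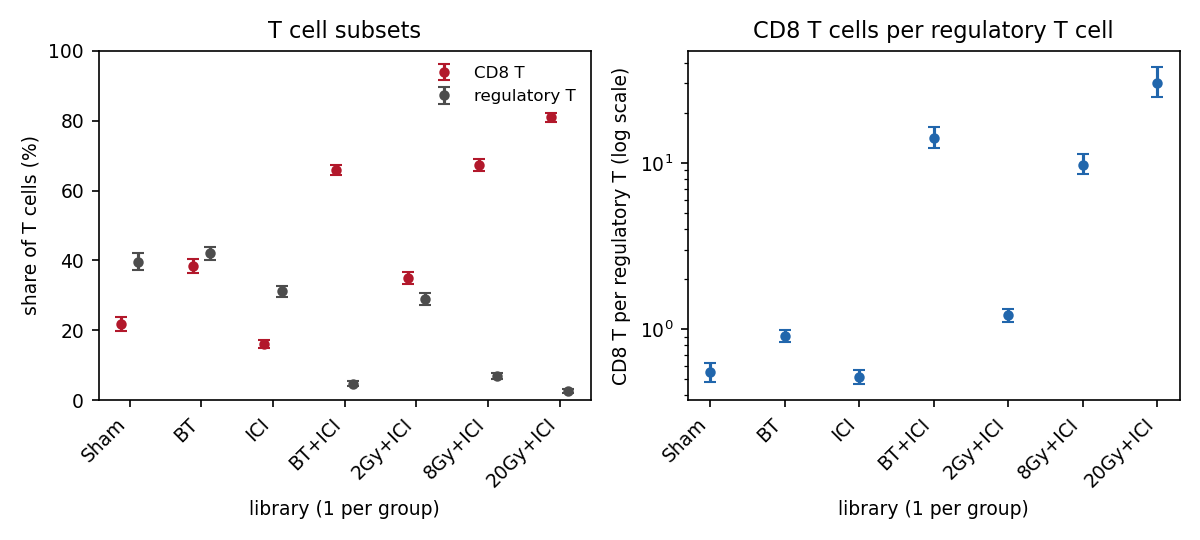
CD8 T and regulatory T cells as shares of T cells and the number of CD8 T cells per regulatory T cell, per library. Bars are 95% counting intervals.

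In CD8 T cells of BT+ICI against ICI the highest ratios were those of Serpinb1a (71.8 CPM against 7.31 CPM, log2 ratio 2.64), Il2ra (54.3 against 7.98, 2.19), Kdm6b (195 against 40.3, 2.14), Nr4a3 (123 against 26.4, 2.03) and Abcb1b (114 against 27.5, 1.87). Il2ra encodes the interleukin 2 receptor alpha chain, and Nr4a3 is induced by T cell receptor signalling. Il7r was at 139 against 41.4 CPM. Of the type I interferon list 29 of 29 members were higher (median 1.02, counting range 0.89 to 1.10), including Isg15 (757 against 244 CPM). Leaving out the cluster with Ifit1 and Ifit3 gave 0.66, and equal weights of the CD8 clusters 0.44. The lowest ratios were those of Tox2 (6.03 against 35.7, -1.88), Nrn1 (27.8 against 112, -1.84), Prss2 (3.22 against 21.1, -1.66), Spry1 (5.16 against 23.3, -1.48) and Jun (116 against 332, -1.47). The cytotoxic list was near 0 (median -0.11), while some of its members were lower, with Ccl3 at 86.6 against 566 CPM, Ccl4 at 393 against 1772, Ccl5 at 7607 against 14826 and Prf1 at 192 against 404. Gzmb was similar (1763 and 1603 CPM). Lag3 (185 against 345) and Tox (221 against 348) were lower, while Pdcd1 was at 513 and 581 CPM. MHC class II transcripts, which come mostly from other cells, were lower (median -0.70), and the stress list was lower (median -0.23).

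Macrophages and monocytes of BT+ICI held both inflammatory and alternative genes at higher levels than those of ICI. The inflammatory list had a median of 0.80 (16 of 21 higher) and the alternative list one of 0.71 (17 of 21 higher). The top ratios were those of Ccl24 (150.1 CPM against 4.97 CPM, log2 ratio 3.96), Ccl17 (92.1 against 4.55, 3.35), Inhba (521 against 92.0, 2.44), Mmp13 (258 against 47.5, 2.33) and Pdcd1lg2 (74.6 against 12.2, 2.21), the gene of PD-L2. Nos2 was at 141 against 40.9 CPM, Arg1 at 1847 against 436, Il1b at 4059.6 against 2329 and Cd274 at 273 against 144. Genes of neutrophil recruitment stood out, with Cxcl1 at 346 against 90.0 CPM, Cxcl2 at 5726 against 1123, and 17 of 20 members of the NF-kB list higher (median 0.66). Type I interferon genes were higher in 29 of 30 cases (median 0.85, counting range 0.82 to 0.90) and interferon gamma genes in 26 of 28 (median 0.43). The lowest ratios were those of Fcrls (18.5 against 264, -3.52), Cd81 (81.2 against 537, -2.65), Hist1h1b (20.6 against 154, -2.64), Cxcl13 (0.731 against 29.6, -2.59) and Tmem176b (71.6 against 378, -2.32). C1qa (3068 against 6168) and Apoe (2874 against 7450.3) were lower as well. G2/M genes had a median of -1.43 and S phase genes one of -0.91. Checkpoint ligand (0.34), TGF-beta (0.25) and oxidative phosphorylation genes (0.31) were higher, DNA repair genes were lower (-0.33) and the complement list was near 0 (-0.20).

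The make-up of the macrophages differed as well. Those with Arg1 and Ly6i, which Ccl24 also marks, were 68.8% of macrophages in BT+ICI and 31.2% in ICI, those with Fcrls and Apoe 5.40% and 32.9%, and cycling macrophages 1.61% and 13.4%. With clusters given the same weight in both libraries the medians were -0.13 for G2/M, -0.25 for S phase, 0.34 for the alternative list and 0.46 for type I interferon genes.

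Brachytherapy was then compared with and without checkpoint antibodies, as the log2 ratio of BT+ICI to ICI less that of BT to Sham. The CD8 to regulatory T cell balance differed most. Its log2 ratio was 4.77 with antibodies and 0.73 without, a difference of 4.04 (3.70 to 4.40). Regulatory T cells gave a difference of -2.82 (-3.07 to -2.59) in their share of T cells, and macrophages one of -0.22 (-0.27 to -0.17) in their share of myeloid cells. The type I interferon list differed the other way in CD8 T cells, by -1.01 (-1.17 to -0.83), and by -0.29 (-0.34 to -0.23) in monocytes and macrophages. Under the alternatives the CD8 difference ran from -1.27 (pseudocount of 1) to -0.32 (equal cluster weights). That of monocytes and macrophages ran from -0.42 (equal cluster weights) to -0.14 (TMM totals), the latter too small for a direction. In BT+ICI against BT, CD8 T cells had lower type I interferon (-0.70), interferon gamma (-0.43) and exhaustion genes (-0.59), with Lag3 at 185 against 346 CPM. Without the cluster with Ifit1 and Ifit3, which held 30.2% of CD8 T cells in BT and 13.4% in BT+ICI, these medians were -0.20, 0.021 and -0.53. Macrophages and monocytes of BT+ICI had higher interferon gamma (0.73), MHC class II (0.49) and inflammatory genes (0.66) than those of BT, with Cd274 at 273 against 80.1 CPM and Nos2 at 141 against 10.5. The log2 ratio of CD8 T to regulatory T cells in BT+ICI against BT was 3.95 (3.71 to 4.21).

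External beam radiation was given at 3 doses with the same antibodies, and 2Gy+ICI, 8Gy+ICI and 20Gy+ICI were each compared with ICI. By clusters, the number of CD8 T cells per regulatory T cell stood higher at each larger dose. Type I interferon genes followed the same order in CD8 T cells and in monocytes and macrophages. Monocytes were a larger part of the myeloid cells at all 3 doses, and the macrophages with Fcrls and Apoe were few at 8 and 20 Gy. There were 1.21, 9.76 and 30.3 (95% interval 24.8 to 37.8) CD8 T cells per regulatory T cell in 2Gy+ICI, 8Gy+ICI and 20Gy+ICI, against 0.517 in ICI. The log2 ratios to ICI were 1.23 (1.04 to 1.42), 4.24 (3.999 to 4.50) and 5.87 (5.55 to 6.23), and that of 20Gy+ICI to 2Gy+ICI was 4.64 (4.32 to 4.98). Gates on single cells gave 1.66, 4.35 and 4.49 against ICI, so the step from 8 to 20 Gy nearly vanished there. Monocytes were 22.05%, 25.9% and 23.8% of myeloid cells against 10.5% in ICI. NK cells were 5.15%, 5.24% and 3.39% of named leukocytes against 2.55%. The log2 ratios to ICI were 1.015, 1.04 and 0.41 by clusters and 0.21, -0.039 and 1.58 by single-cell gates, so the direction for 8Gy+ICI was not stable.

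In CD8 T cells the genes highest over ICI at all 3 doses, with CPM in ICI and then at 2, 8 and 20 Gy, were Serpinb1a (7.31 in ICI and 26.5, 28.3 and 52.3, log2 ratios 1.35, 1.44 and 2.22), Nr4a3 (26.4 in ICI and 63.5, 107 and 94.0, log2 ratios 1.13, 1.83 and 1.66), Ifit2 (29.9 in ICI and 70.4, 99.3 and 122), Rnf213 (55.9 in ICI and 122, 212 and 263) and Ifi211 (13.7 in ICI and 33.6, 59.8 and 56.9). The type I interferon list had medians of 0.75, 1.25 and 1.56 against ICI, and of 0.30, 0.49 and 0.57 with CD8 clusters weighted equally. Isg15 (ENSMUSG00000035692) was at 244 CPM in ICI and at 488, 898 and 893. Cdkn1a, a target of p53, was at 45.4 CPM in ICI and 88.2, 134 and 190.3 after radiation, although the p53 list as a whole stayed near 0 (0.08, -0.07 and 0.09). Il2ra (7.98, then 18.2, 31.9 and 76.1 CPM) was higher as well. The genes lowest against ICI were Prss2 (21.1 in ICI and 3.01, 0.308 and 0.386, log2 ratios -1.70, -2.30 and -2.27), Nrn1 (112 in ICI and 60.8, 12.3 and 14.1), Tff1 (39.9 in ICI and 20.5, 15.5 and 14.1), Ccl5 (14826 in ICI and 8639, 8908 and 6018) and Jun (332 in ICI and 206, 96.1 and 102). G2/M genes were higher (0.42, 0.30 and 0.38), interferon gamma genes had medians of 0.29, 0.32 and 0.58, and MHC class II transcripts were lower at 8 and 20 Gy (-0.69 and -0.69). Equal cluster weights turned the interferon gamma median at 8 Gy to -0.15.

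Among monocytes and macrophages the highest genes at all 3 doses were Ly6c2 (154 in ICI and 487, 1132 and 836, log2 ratios 1.63, 2.84 and 2.41), Chil3 (146 in ICI and 515, 458 and 797), Plac8 (447 in ICI and 1204, 1929 and 1731), Ms4a4c (265 in ICI and 626, 785 and 919) and Ccl24 (4.97 in ICI and 17.3, 174 and 256, log2 ratios 1.16, 4.17 and 4.71). Ly6c2, Chil3 and Plac8 are genes of monocytes, and the cluster with Chil3 and Vcan held 60.9%, 51.3% and 68.3% of monocytes against 45.6% in ICI. Type I interferon genes had medians of 0.66, 0.97 and 1.32 and interferon gamma genes of 0.17, 0.25 and 0.56. With equal cluster weights the type I interferon medians were 0.24, 0.48 and 0.69. The alternative list was higher at each dose (0.30, 0.38 and 0.77), with Arg1 at 436 CPM in ICI and 585, 909 and 1979. The inflammatory list was higher only at 20 Gy (0.02, 0.05 and 0.27). The lowest genes were Cxcl13 (29.6 in ICI and 10.1, 3.41 and 0.369), Rrad (35.9 in ICI and 13.3, 11.97 and 7.30), Klrb1b (61.0 in ICI and 29.4, 29.7 and 23.9), Cenpe (33.6 in ICI and 18.1, 10.4 and 16.03) and Cxcl14 (22.2 in ICI and 11.3, 3.26 and 1.84). The G2/M list was lower (-0.39, -1.06 and -0.89), and cycling macrophages, which Cenpe marks, were 13.4% of macrophages in ICI and 8.03%, 4.19% and 4.07% after radiation. With equal cluster weights the G2/M medians were 0.11, -0.13 and 0.19, and the log2 ratio of Cenpe at 20 Gy turned to 0.46. T cell chemokine genes were lower at 8 Gy (0.00, -0.57 and -0.24, and -0.06 at 8 Gy with equal cluster weights), with Cxcl9 at 1893 CPM in ICI and 1524, 1175 and 889. Macrophages with Arg1 and Ly6i were 31.2% of macrophages in ICI and 42.8%, 70.3% and 69.1% after radiation. Those with Fcrls and Apoe were 32.9% and then 26.9%, 7.64% and 4.86%. Oxidative phosphorylation genes were lower at 2 Gy and higher at 8 Gy (-0.46, 0.30 and 0.12).

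The lists of neutrophil, fibroblast and melanoma free RNA were highest in 20Gy+ICI. In monocytes and macrophages, neutrophil transcripts such as S100a8 were at 5.27, 3.999, 17.3, 39.0, 13.3, 21.3 and 185 CPM in Sham, BT, ICI, BT+ICI, 2Gy+ICI, 8Gy+ICI and 20Gy+ICI, and those of the fibroblast list at 15.5, 25.5, 14.2, 26.3, 6.21, 49.4 and 98.9. The fibroblast list holds Mgp and Sparc, leading genes of the Ptprc-low cluster with Apod, Mgp and Sox10. That cluster was also largest in 20Gy+ICI (10.6% of cells kept). Col1a1, another member, was at only 0.146 CPM in the largest CD8 cluster and 1.94 CPM in the Ptprc-low cluster. CD8 T cells had neutrophil transcripts at 1.37, 1.99, 2.66, 7.39, 3.01, 6.96 and 11.7 and those of the fibroblast list at 17.4, 24.2, 20.6, 27.4, 6.66, 53.4 and 119.6. Melanoma transcripts were at 2.05, 1.99, 1.55, 2.07, 1.11, 4.13 and 7.18 in CD8 T cells and at 4.55, 4.48, 2.08, 4.28, 2.28, 4.95 and 8.61 in monocytes and macrophages. Red blood cell transcripts in monocytes and macrophages were at 0.261, 0.0889, 0.299, 0.0844, 0.136, 0.9755 and 0.0410, and in CD8 T cells at 0, 0, 0, 0.124, 0, 0.0616 and 0.

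The last comparison set the uneven dose of brachytherapy against external beam doses, by comparing BT+ICI with 2Gy+ICI, 8Gy+ICI and 20Gy+ICI. By clusters, its CD8 and regulatory T cell shares were closer to those of 8Gy+ICI and 20Gy+ICI than to those of 2Gy+ICI. Its monocytes and macrophages, summed together, had higher Cxcl1, Ptgs2, Il1b, Vegfa and Nlrp3 than at all 3 doses. Its neutrophil share was the largest. The log2 ratios of CD8 T to regulatory T cells were 3.54 (3.29 to 3.80) against 2Gy+ICI, 0.53 (0.23 to 0.83) against 8Gy+ICI and -1.10 (-1.49 to -0.73) against 20Gy+ICI. Single-cell gates gave 2.55, -0.14 and -0.28, so the direction against 8Gy+ICI was not stable. Neutrophils were 15.6% (95% interval 14.3 to 16.9) of myeloid cells against 4.93%, 6.88% and 7.26%, and monocytes 12.2% against 22.05%, 25.9% and 23.8%. DC were 5.19% against 10.1%, 7.64% and 6.77%, but gates on single cells turned the log2 ratio to 8Gy+ICI from -0.56 to 1.21. For neutrophils the gates gave log2 ratios of 2.55, 1.42 and 0.27, against 1.66, 1.18 and 1.10 by clusters.

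In monocytes and macrophages the genes highest in BT+ICI against all 3 doses, with CPM in BT+ICI and then at 2, 8 and 20 Gy, were Cxcl1 (346 against 94.7, 51.5 and 102, log2 ratios 1.82, 2.64 and 1.72), Ptgs2 (702 against 248, 230.5 and 281, log2 ratios 1.49, 1.59 and 1.31), Vegfa (303 against 114, 105 and 122), Grasp (48.3 against 17.04, 19.6 and 19.6) and Nlrp3 (331 against 68.1, 104 and 151). Cxcl1 attracts neutrophils, Ptgs2 encodes the prostaglandin enzyme COX-2, and Nlrp3 is a sensor of the inflammasome that activates interleukin 1 beta. Il1b was at 4059.6 CPM against 1962, 1793 and 1775, Cxcl2 at 5726 against 1263, 1983 and 3469.6, and Mmp12 at 1651 against 533, 645 and 1011. The NF-kB list had medians of 0.65, 0.56 and 0.43 and the inflammatory list of 0.74, 0.52 and 0.41, while the alternative list was nearer 0 (0.19, 0.22 and -0.12). Hypoxia genes were higher than in 8Gy+ICI (0.20, 0.33 and 0.02). The lowest genes were Fcrls (18.5 against 361, 42.1 and 61.2, log2 ratios -3.96, -1.002 and -1.49), Ifitm6 (28.6 against 56.3, 91.7 and 58.7), Pou2f2 (50.5 against 96.3, 114 and 92.5), Pclaf (17.2 against 55.4, 39.9 and 31.8) and Cdca3 (5.20 against 26.5, 11.9 and 14.9). Fcrls marks a macrophage cluster that was 5.40% of macrophages in BT+ICI and 26.9% in 2Gy+ICI, where macrophages with Arg1 and Ly6i were 42.8% against 68.8% in BT+ICI. Ifitm6 is a leading gene of both monocyte clusters. Monocytes were 12.2% of myeloid cells in BT+ICI against 22.05%, 25.9% and 23.8% at the 3 doses. Type I interferon genes were higher than in 2Gy+ICI and lower than in 20Gy+ICI (0.24, -0.16 and -0.43). Neither direction held under every alternative. The median against 20Gy+ICI fell under 0.2 in size with equal cluster weights, and that against 2Gy+ICI did so with thinned cells.

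CD8 T cells of BT+ICI were set against the same 3 libraries. The highest genes were Fbxo32 (34.2 against 13.8, 15.2 and 16.8, log2 ratios 1.06, 0.95 and 0.85), Mxi1 (212 against 118.995, 122 and 122), Crem (201 against 125, 129.6 and 129), Orai1 (264 against 175, 159 and 169.7) and Gch1 (107 against 71.2, 56.6 and 67.7). The lowest were Il10ra (48.2 against 97.1, 96.4 and 92.1, log2 ratios -0.94, -0.93 and -0.87), Ddit3 (40.7 against 66.8, 64.8 and 67.2), Zfpm1 (17.8 against 28.4, 31.4 and 30.9), Cdkn2a (15.7 against 33.3, 25.8 and 23.9) and Ptpn6 (83.02 against 159, 116 and 135). Type I interferon genes had medians of 0.29, -0.29 and -0.51, which places BT+ICI between 2Gy+ICI and 8Gy+ICI. With equal cluster weights each of these medians was under 0.2 in size, so this placement was not stable. Oxidative phosphorylation genes were higher than in 2Gy+ICI in CD8 T cells (0.73) as in monocytes and macrophages (0.72). Exhaustion genes were lower than in 2Gy+ICI (-0.37, -0.12 and -0.01), and cytotoxic genes were higher than in 8Gy+ICI (-0.19, 0.21 and -0.06), with Gzmb at 1763 CPM against 1486. The number of UMIs per cell was lowest in 2Gy+ICI, and the median log2 ratio over all genes in CD8 T cells was -0.12 for BT+ICI against 2Gy+ICI. The largest such shift in any class was -0.17, in CD4 conventional T cells for the same libraries. No gene given among the highest or lowest changed direction with TMM scaling.

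**Figure D4:**
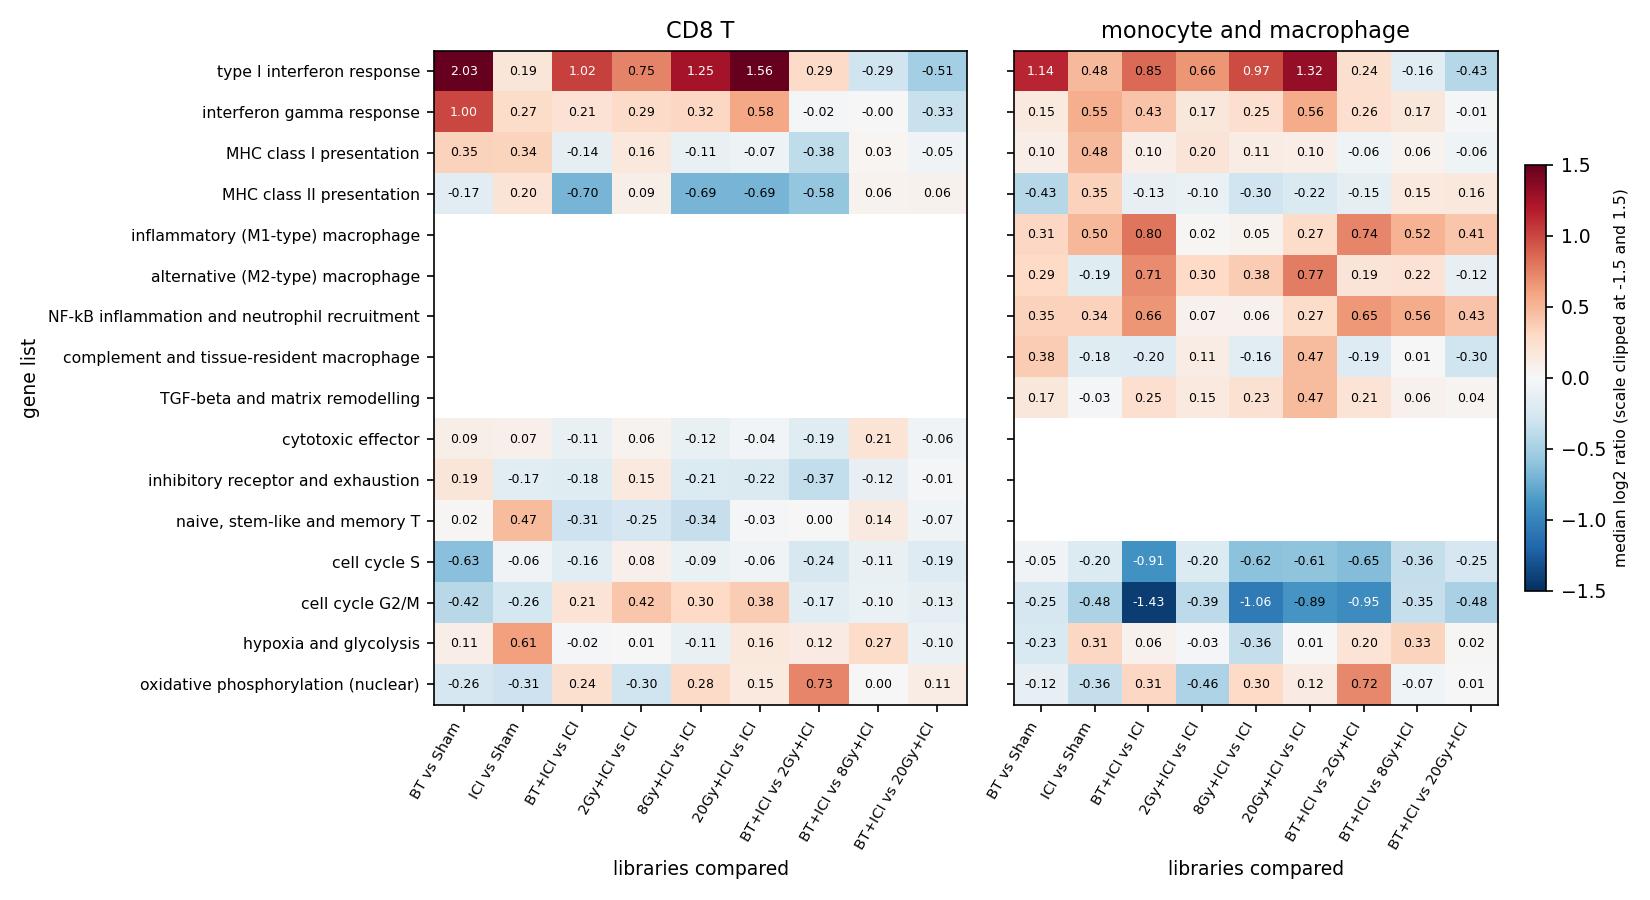
Median log2 ratios of 16 gene lists in CD8 T cells and in monocytes and macrophages for 9 comparisons. Blank fields are lists not read in that class, and the colours stop at the ends of the scale.

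Genes of the p53 response were close to even in most comparisons. For BT against Sham, ICI against Sham and BT+ICI against ICI, the p53 list had medians of -0.03, 0.09 and -0.10 in CD8 T cells and 0.10, 0.00 and 0.07 in monocytes and macrophages. In monocytes and macrophages of 20Gy+ICI against ICI it was 0.21. The list of cGAS-STING and type I interferon genes, which include Cgas and Tbk1, had medians of 0.15, 0.18 and -0.09 and 0.11, 0.12 and -0.15. Cytotoxic genes in CD8 T cells were at 0.09, 0.07 and -0.11 and exhaustion genes at 0.19, -0.17 and -0.18. The regulatory activation list was at -0.03, 0.31 and 0.05 in CD8 T cells. In monocytes and macrophages, lipid-associated genes such as Trem2 were at 0.22, 0.08 and 0.02, T cell chemokine genes at 0.12, 0.22 and -0.13, checkpoint ligands at 0.22, 0.16 and 0.34, TGF-beta and matrix genes at 0.17, -0.03 and 0.25 and stress genes at 0.18, 0.10 and 0.14. Naive and memory genes in CD8 T cells were lower in BT+ICI than in ICI (-0.31), but reached 0.06 with cells thinned to 2000 UMIs. Hypoxia genes in CD8 T cells were at 0.11, 0.61 and -0.02, and nuclear oxidative phosphorylation genes at -0.26, -0.31 and 0.24.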

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

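Values for brachytherapy had opposite signs in the libraries without and with checkpoint antibodies in 5 measures, each time beyond counting error and, for gene lists, outside the middle 95% of random lists in both comparisons. These differences between groups were not tested. The log2 ratio of the DC share of myeloid cells was 0.29 for BT against Sham and -0.52 for BT+ICI against ICI, a difference of -0.82. For neutrophils the ratios were -0.66 and 2.68, a difference of 3.35. The first of these rests on 35 neutrophils in BT and 49 in Sham, and its counting range (-1.31 to -0.03) nearly reached 0. G2/M genes in CD8 T cells had medians of -0.42 and 0.21, a difference of 0.62. Nuclear oxidative phosphorylation genes had medians of -0.26 and 0.24 in CD8 T cells, a difference of 0.49, and of -0.12 and 0.31 in monocytes and macrophages, a difference of 0.44. Of these values -0.12 is below the size of 0.2 log2 from which a direction is given, so that an opposite direction is not claimed for monocytes and macrophages. Other lists had opposite signs but lay within that range of random lists for BT+ICI against ICI, among them mitochondrially encoded genes (-0.42 and 0.12) and MHC class I genes (0.35 and -0.14) in CD8 T cells and the complement list in monocytes and macrophages (0.38 and -0.20). With equal cluster weights the difference of the G2/M medians in CD8 T cells was -0.17.

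Outside the named classes, clusters stood out where the 95% interval of their share lay above that of Sham, a difference that was not tested. Cells with Trdc and Klra7 were 4.97% of cells kept in BT and 6.71% in 20Gy+ICI, against 3.87% in Sham. Cells with Apod, Mgp and Sox10, low in Ptprc despite the sort for CD45, were 3.90% in BT+ICI, 8.42% in 8Gy+ICI and 10.6% in 20Gy+ICI, against 2.41% in Sham. Clusters with few UMIs per cell stood out too. That with T cell genes held 3.20% of cells kept in BT, 3.23% in ICI, 8.27% in BT+ICI, 11.5% in 2Gy+ICI, 18.1% in 8Gy+ICI and 2.78% in 20Gy+ICI, against 0.676% in Sham. That with mixed genes at the lowest UMI counts held 7.07% of cells kept in BT+ICI, 0.870% in 2Gy+ICI, 9.36% in 8Gy+ICI and 1.51% in 20Gy+ICI, against 0.351% in Sham. A further low-UMI cluster, with macrophage and T cell genes, was largest in Sham, with shares of 16.8, 5.81, 10.4, 1.006, 4.44, 0.499 and 0.907% in Sham, BT, ICI, BT+ICI, 2Gy+ICI, 8Gy+ICI and 20Gy+ICI. What these clusters hold was not settled here, and none of them enters the comparisons of expression as reported.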

How the results depend on the processing

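The alternatives that gave low-UMI clusters a class, left out the naive-type T and B clusters, corrected for transcript length or left out the CD8 cluster with Ifit1 and Ifit3 were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and leaving out a library would leave a group empty. All values are log2 ratios, or medians of log2 ratios for gene lists, and the value as reported follows in parentheses. A sign change is counted only where the reported value is at least 0.2 in size and its counting range leaves out 0. The cause of each difference was not tested. Among alternative values of list medians, 2893 of 4367 stayed within the counting range and 16 were counted as sign changes. For shares these were 820 of 1089 and 12, for CD8 T per regulatory T cell 90 of 110 and 1, for named genes 1081 of 1842 and 1, and for brachytherapy with less without ICI 126 of 163 and 1. Given by alternative are all counted sign changes, and the values beyond the counting range for the T cell share, the macrophage share, CD8 T per regulatory T cell and type I interferon genes, some of which also differ in sign from a reported value too small to count. Values of other measures beyond that range are only counted.

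Gates on single cells gave, for CD8 T per regulatory T cell, 0.98 (0.73) for BT against Sham, 0.69 (-0.09) for ICI against Sham, 4.21 (4.77) for BT+ICI against ICI, 1.66 (1.23) for 2Gy+ICI against ICI and 4.49 (5.87) for 20Gy+ICI against ICI. The next were 2.55 (3.54) for BT+ICI against 2Gy+ICI, -0.14 (0.53) for BT+ICI against 8Gy+ICI, -0.28 (-1.10) for BT+ICI against 20Gy+ICI, 2.83 (4.64) for 20Gy+ICI against 2Gy+ICI and 3.23 (4.04) for brachytherapy with less without ICI. The T cell share was 0.52 (0.35) for BT against Sham, 0.97 (0.74) for ICI against Sham, 0.68 (0.62) for BT+ICI against BT, 0.22 (-0.08) for 2Gy+ICI against ICI and 0.36 (0.18) for 8Gy+ICI against ICI. The remaining values were 0.10 (0.39) for 20Gy+ICI against ICI, 0.019 (0.31) for BT+ICI against 2Gy+ICI, -0.12 (0.05) for BT+ICI against 8Gy+ICI, 0.14 (-0.16) for BT+ICI against 20Gy+ICI and -0.12 (0.47) for 20Gy+ICI against 2Gy+ICI. For the macrophage share the values were -0.021 (-0.07) for ICI against Sham, -0.24 (-0.34) for 2Gy+ICI against ICI, -0.27 (-0.42) for 8Gy+ICI against ICI, -0.42 (-0.36) for 20Gy+ICI against ICI and -0.040 (0.09) for BT+ICI against 2Gy+ICI. Others were -0.0092 (0.17) for BT+ICI against 8Gy+ICI and -0.18 (-0.02) for 20Gy+ICI against 2Gy+ICI. The direction was the other one for the CD8 share of T cells, at 0.10 (-0.44) for ICI against Sham, the regulatory share of T cells, at 0.13 (-0.56) for BT+ICI against 8Gy+ICI, and the CD4 conventional share of T cells, at -0.061 (0.79) for BT+ICI against BT. It also changed for the NK share, at -0.039 (1.04) for 8Gy+ICI against ICI, 0.16 (-0.90) for BT+ICI against 8Gy+ICI and 1.37 (-0.61) for 20Gy+ICI against 2Gy+ICI, and the DC share, at 1.21 (-0.56) for BT+ICI against 8Gy+ICI.

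Giving low-UMI clusters a class gave, for CD8 T per regulatory T cell, 0.31 (-0.09) for ICI against Sham, 1.57 (1.23) for 2Gy+ICI against ICI, 4.51 (4.24) for 8Gy+ICI against ICI, 5.38 (5.87) for 20Gy+ICI against ICI and 2.98 (3.54) for BT+ICI against 2Gy+ICI. More values were 0.039 (0.53) for BT+ICI against 8Gy+ICI, 3.80 (4.64) for 20Gy+ICI against 2Gy+ICI and 3.66 (4.04) for brachytherapy with less without ICI. The T cell share was 0.60 (0.35) for BT against Sham, 0.89 (0.74) for ICI against Sham, 0.43 (0.23) for BT+ICI against ICI, 0.72 (0.62) for BT+ICI against BT and 0.17 (-0.08) for 2Gy+ICI against ICI. Then came 0.54 (0.18) for 8Gy+ICI against ICI, 0.51 (0.39) for 20Gy+ICI against ICI, -0.11 (0.05) for BT+ICI against 8Gy+ICI, -0.083 (-0.16) for BT+ICI against 20Gy+ICI and 0.35 (0.47) for 20Gy+ICI against 2Gy+ICI. For the macrophage share the values were -0.063 (-0.03) for BT against Sham, -0.31 (-0.25) for BT+ICI against ICI, -0.48 (-0.42) for 8Gy+ICI against ICI and 0.030 (0.09) for BT+ICI against 2Gy+ICI.

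Centring components per library gave, for CD8 T per regulatory T cell, 4.42 (4.77) for BT+ICI against ICI, 3.86 (4.24) for 8Gy+ICI against ICI and 5.49 (5.87) for 20Gy+ICI against ICI. The macrophage share was -0.20 (-0.25) for BT+ICI against ICI, -0.25 (-0.29) for BT+ICI against BT, -0.29 (-0.34) for 2Gy+ICI against ICI and -0.27 (-0.36) for 20Gy+ICI against ICI.

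Allowing only 5% mitochondrial counts gave, for CD8 T per regulatory T cell, 4.31 (4.64) for 20Gy+ICI against 2Gy+ICI. For the T cell share the values were 0.30 (0.23) for BT+ICI against ICI, -0.16 (-0.08) for 2Gy+ICI against ICI, 0.25 (0.18) for 8Gy+ICI against ICI, 0.48 (0.39) for 20Gy+ICI against ICI and 0.46 (0.31) for BT+ICI against 2Gy+ICI. Further values were 0.64 (0.47) for 20Gy+ICI against 2Gy+ICI. The macrophage share was -0.15 (-0.03) for BT against Sham, -0.19 (-0.29) for BT+ICI against BT, -0.54 (-0.42) for 8Gy+ICI against ICI and 0.27 (0.17) for BT+ICI against 8Gy+ICI. The sign changed for the monocyte share, at -0.18 (0.57) for BT+ICI against BT.

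Resolution 0.5 gave, for the T cell share, 0.53 (0.35) for BT against Sham, 0.63 (0.74) for ICI against Sham, 0.53 (0.23) for BT+ICI against ICI, 0.11 (-0.08) for 2Gy+ICI against ICI and 0.43 (0.18) for 8Gy+ICI against ICI. The next were 0.70 (0.39) for 20Gy+ICI against ICI, 0.41 (0.31) for BT+ICI against 2Gy+ICI and 0.59 (0.47) for 20Gy+ICI against 2Gy+ICI. For the macrophage share the values were -0.25 (-0.29) for BT+ICI against BT, -0.25 (-0.36) for 20Gy+ICI against ICI and 0.034 (0.11) for BT+ICI against 20Gy+ICI. The direction was the other one for the NK share, at 0.16 (-0.61) for 20Gy+ICI against 2Gy+ICI, and the monocyte share, at -0.047 (0.22) for BT+ICI against ICI.

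Allowing 20% mitochondrial counts gave, for the T cell share, 0.18 (0.23) for BT+ICI against ICI, 0.30 (0.39) for 20Gy+ICI against ICI, 0.24 (0.31) for BT+ICI against 2Gy+ICI and 0.36 (0.47) for 20Gy+ICI against 2Gy+ICI. The macrophage share was 0.014 (-0.03) for BT against Sham, -0.15 (-0.25) for BT+ICI against ICI, -0.20 (-0.29) for BT+ICI against BT, -0.17 (-0.34) for 2Gy+ICI against ICI and -0.25 (-0.42) for 8Gy+ICI against ICI. The remaining values were -0.15 (-0.36) for 20Gy+ICI against ICI, 0.019 (0.09) for BT+ICI against 2Gy+ICI and 0.0068 (0.11) for BT+ICI against 20Gy+ICI. Sign changes were found for the monocyte share, at -0.34 (0.22) for BT+ICI against ICI.

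Without doublet removal, the T cell share was 0.70 (0.62) for BT+ICI against BT and 0.27 (0.18) for 8Gy+ICI against ICI. For the macrophage share the values were -0.086 (-0.03) for BT against Sham, -0.48 (-0.42) for 8Gy+ICI against ICI, -0.44 (-0.36) for 20Gy+ICI against ICI and -0.090 (-0.02) for 20Gy+ICI against 2Gy+ICI. For interferon-stimulated genes in CD8 T cells the values were 0.61 (0.75) for 2Gy+ICI against ICI. The type I interferon list in monocytes and macrophages was 0.41 (0.48) for ICI against Sham, 0.82 (0.85) for BT+ICI against ICI, 0.26 (0.32) for BT+ICI against BT and 0.94 (0.97) for 8Gy+ICI against ICI.

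Requiring 500 genes per cell gave, for the macrophage share, -0.17 (-0.25) for BT+ICI against ICI, -0.22 (-0.29) for BT+ICI against BT, -0.29 (-0.34) for 2Gy+ICI against ICI, -0.36 (-0.42) for 8Gy+ICI against ICI and -0.25 (-0.36) for 20Gy+ICI against ICI.

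A pseudocount of 1 gave, for type I interferon in CD8 T cells, 2.40 (2.03) for BT against Sham, 1.14 (1.02) for BT+ICI against ICI, 0.90 (0.75) for 2Gy+ICI against ICI, 1.38 (1.25) for 8Gy+ICI against ICI and 1.68 (1.56) for 20Gy+ICI against ICI. Others were -0.35 (-0.29) for BT+ICI against 8Gy+ICI and -1.27 (-1.01) for brachytherapy with less without ICI. Interferon-stimulated genes in monocytes and macrophages had 1.27 (1.14) for BT against Sham, 0.58 (0.48) for ICI against Sham, 0.36 (0.32) for BT+ICI against BT, 0.72 (0.66) for 2Gy+ICI against ICI and 1.05 (0.97) for 8Gy+ICI against ICI. More values were 1.41 (1.32) for 20Gy+ICI against ICI and -0.38 (-0.29) for brachytherapy with less without ICI.

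A pseudocount of 20 gave, for type I interferon in CD8 T cells, 1.47 (2.03) for BT against Sham, 0.71 (1.02) for BT+ICI against ICI, -0.55 (-0.70) for BT+ICI against BT, 0.51 (0.75) for 2Gy+ICI against ICI and 0.91 (1.25) for 8Gy+ICI against ICI. Then came 1.12 (1.56) for 20Gy+ICI against ICI, 0.25 (0.29) for BT+ICI against 2Gy+ICI, -0.24 (-0.29) for BT+ICI against 8Gy+ICI, -0.42 (-0.51) for BT+ICI against 20Gy+ICI and 0.65 (0.75) for 20Gy+ICI against 2Gy+ICI. Further values were -0.76 (-1.01) for brachytherapy with less without ICI. Type I interferon in monocytes and macrophages was 0.87 (1.14) for BT against Sham, 0.40 (0.48) for ICI against Sham, 0.69 (0.85) for BT+ICI against ICI, 0.28 (0.32) for BT+ICI against BT and 0.49 (0.66) for 2Gy+ICI against ICI. The next were 0.82 (0.97) for 8Gy+ICI against ICI, 1.11 (1.32) for 20Gy+ICI against ICI, -0.39 (-0.43) for BT+ICI against 20Gy+ICI, 0.65 (0.72) for 20Gy+ICI against 2Gy+ICI and -0.18 (-0.29) for brachytherapy with less without ICI.

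Equal cluster weights gave, for type I interferon in CD8 T cells, 0.76 (2.03) for BT against Sham, 0.44 (1.02) for BT+ICI against ICI, -0.22 (-0.70) for BT+ICI against BT, 0.30 (0.75) for 2Gy+ICI against ICI and 0.49 (1.25) for 8Gy+ICI against ICI. The remaining values were 0.57 (1.56) for 20Gy+ICI against ICI, 0.10 (0.29) for BT+ICI against 2Gy+ICI, -0.036 (-0.29) for BT+ICI against 8Gy+ICI, -0.15 (-0.51) for BT+ICI against 20Gy+ICI and 0.24 (0.75) for 20Gy+ICI against 2Gy+ICI. Others were -0.32 (-1.01) for brachytherapy with less without ICI. For interferon-stimulated genes in monocytes and macrophages the values were 0.88 (1.14) for BT against Sham, 0.41 (0.48) for ICI against Sham, 0.46 (0.85) for BT+ICI against ICI, -0.021 (0.32) for BT+ICI against BT and 0.24 (0.66) for 2Gy+ICI against ICI. More values were 0.48 (0.97) for 8Gy+ICI against ICI, 0.69 (1.32) for 20Gy+ICI against ICI, 0.29 (0.24) for BT+ICI against 2Gy+ICI, -0.065 (-0.16) for BT+ICI against 8Gy+ICI and -0.16 (-0.43) for BT+ICI against 20Gy+ICI. Then came 0.47 (0.72) for 20Gy+ICI against 2Gy+ICI and -0.42 (-0.29) for brachytherapy with less without ICI. The sign changed for G2/M in CD8 T cells, at 0.26 (-0.42) for BT against Sham, -0.32 (0.34) for BT+ICI against BT and -0.17 (0.62) for brachytherapy with less without ICI, interferon gamma in CD8 T cells, at -0.050 (0.21) for BT+ICI against ICI and -0.15 (0.32) for 8Gy+ICI against ICI, and S phase in CD8 T cells, at -0.023 (0.39) for BT+ICI against BT. It also changed for G2/M in monocytes and macrophages, at 0.089 (-0.25) for BT against Sham, 0.11 (-0.39) for 2Gy+ICI against ICI, 0.19 (-0.89) for 20Gy+ICI against ICI, 0.012 (-0.35) for BT+ICI against 8Gy+ICI and 0.13 (-0.49) for 20Gy+ICI against 2Gy+ICI, S phase in monocytes and macrophages, at 0.10 (-0.20) for ICI against Sham and 0.078 (-0.20) for 2Gy+ICI against ICI, and DNA repair in monocytes and macrophages, at 0.063 (-0.29) for 8Gy+ICI against ICI. It also changed for Cenpe in monocytes and macrophages, at 0.46 (-0.88) for 20Gy+ICI against ICI.

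Leaving out the CD8 cluster with Ifit1 and Ifit3 gave, for type I interferon in CD8 T cells, 1.11 (2.03) for BT against Sham, 0.66 (1.02) for BT+ICI against ICI, -0.20 (-0.70) for BT+ICI against BT, 0.34 (0.75) for 2Gy+ICI against ICI and 0.78 (1.25) for 8Gy+ICI against ICI. Further values were 1.12 (1.56) for 20Gy+ICI against ICI, -0.21 (-0.29) for BT+ICI against 8Gy+ICI, -0.46 (-0.51) for BT+ICI against 20Gy+ICI and -0.44 (-1.01) for brachytherapy with less without ICI. The sign changed for interferon gamma in CD8 T cells, at 0.021 (-0.43) for BT+ICI against BT.

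With TMM totals, type I interferon in CD8 T cells was 0.11 (0.19) for ICI against Sham, 1.13 (1.02) for BT+ICI against ICI, 1.60 (1.56) for 20Gy+ICI against ICI, 0.47 (0.29) for BT+ICI against 2Gy+ICI and -0.43 (-0.51) for BT+ICI against 20Gy+ICI. The next were 0.85 (0.75) for 20Gy+ICI against 2Gy+ICI. The type I interferon list in monocytes and macrophages was 1.08 (1.14) for BT against Sham, 0.94 (0.85) for BT+ICI against ICI, 0.49 (0.32) for BT+ICI against BT, 1.25 (1.32) for 20Gy+ICI against ICI and 0.37 (0.24) for BT+ICI against 2Gy+ICI. The remaining values were -0.10 (-0.16) for BT+ICI against 8Gy+ICI, -0.28 (-0.43) for BT+ICI against 20Gy+ICI, 0.68 (0.72) for 20Gy+ICI against 2Gy+ICI and -0.14 (-0.29) for brachytherapy with less without ICI.

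Totals without mitochondrial, ribosomal protein and receptor genes gave, for type I interferon in CD8 T cells, 0.10 (0.19) for ICI against Sham, 1.13 (1.02) for BT+ICI against ICI, 1.38 (1.25) for 8Gy+ICI against ICI, 1.64 (1.56) for 20Gy+ICI against ICI and 0.39 (0.29) for BT+ICI against 2Gy+ICI. Others were 0.85 (0.75) for 20Gy+ICI against 2Gy+ICI. Interferon-stimulated genes in monocytes and macrophages had 0.43 (0.48) for ICI against Sham, 1.04 (0.97) for 8Gy+ICI against ICI, 0.28 (0.24) for BT+ICI against 2Gy+ICI and 0.76 (0.72) for 20Gy+ICI against 2Gy+ICI.

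Transcript length correction gave, for type I interferon in CD8 T cells, 1.10 (1.02) for BT+ICI against ICI, 1.37 (1.25) for 8Gy+ICI against ICI, 1.65 (1.56) for 20Gy+ICI against ICI, 0.49 (0.29) for BT+ICI against 2Gy+ICI and -0.45 (-0.51) for BT+ICI against 20Gy+ICI. Type I interferon in monocytes and macrophages was 0.40 (0.32) for BT+ICI against BT, 1.03 (0.97) for 8Gy+ICI against ICI, 1.27 (1.32) for 20Gy+ICI against ICI, 0.28 (0.24) for BT+ICI against 2Gy+ICI and -0.35 (-0.43) for BT+ICI against 20Gy+ICI. More values were 0.64 (0.72) for 20Gy+ICI against 2Gy+ICI.

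Thinning cells to 2000 UMIs gave, for type I interferon in CD8 T cells, -0.63 (-0.70) for BT+ICI against BT, 0.95 (0.75) for 2Gy+ICI against ICI, 1.41 (1.25) for 8Gy+ICI against ICI, 1.67 (1.56) for 20Gy+ICI against ICI and 0.26 (0.29) for BT+ICI against 2Gy+ICI. Then came -0.55 (-0.51) for BT+ICI against 20Gy+ICI. For interferon-stimulated genes in monocytes and macrophages the values were 0.53 (0.48) for ICI against Sham, 0.78 (0.85) for BT+ICI against ICI, 0.21 (0.32) for BT+ICI against BT, 0.62 (0.66) for 2Gy+ICI against ICI and 0.86 (0.97) for 8Gy+ICI against ICI. Further values were 1.17 (1.32) for 20Gy+ICI against ICI, 0.14 (0.24) for BT+ICI against 2Gy+ICI and -0.068 (-0.16) for BT+ICI against 8Gy+ICI. The direction was the other one for naive and memory genes in CD8 T cells, at 0.058 (-0.31) for BT+ICI against ICI.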

Other observations

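The tests of lymph node tissue, of checkpoint antibodies without radiation and of a step with each radiation dose were chosen only after the results were seen. Those of transcript length and of the CD8 cluster with Ifit1 and Ifit3 used alternatives that were also chosen after seeing the data. Regulatory T cells and DC shared part of what was seen in CD8 T cells and macrophages. In regulatory T cells the type I interferon list had medians of 1.59 for BT against Sham, 0.12 for ICI against Sham, and 0.67 and 1.58 for 2Gy+ICI and 8Gy+ICI against ICI. The regulatory activation list, which includes Ctla4 and Tnfrsf9, was higher than in Sham in BT (19 of 24, median 0.32) and in ICI (17 of 24, median 0.26). It was near 0 in 2Gy+ICI against ICI (-0.045) and lower in 8Gy+ICI than in ICI (-0.38). Regulatory T cells were few in 8Gy+ICI. Macrophage genes moved the same way in these cells, with the complement list at 0.42 and -0.57 and the lipid-associated list at 0.30 and -0.33. S phase genes in regulatory T cells were higher in ICI than in Sham (21 of 22, median 0.48). Other comparisons of regulatory T cells and DC had fewer than 200 cells in a library and were not read.

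Type I interferon genes in DC had medians of 0.998 for BT against Sham, 0.32 for ICI against Sham and 0.49 for 2Gy+ICI against ICI. The interferon gamma list in DC was higher in BT (0.43) and ICI (0.51) than in Sham, and so were MHC class I genes (0.31 and 0.50). Lists made for T cells were higher in DC too, with the cytotoxic list at 0.58 and 0.57, regulatory activation at 0.60 and 0.26 and exhaustion at 0.48 and 0.27 for BT and ICI against Sham. Some of their members, such as Tnfrsf4 and Serpinb6b, were also markers of Ccr7+ DC in the naming of clusters. Cd3e was at 15.3 and 9.36 CPM in the DC clusters against 906 CPM in the largest CD8 cluster. Whether these values came from free RNA, from genes that DC express or from the make-up of DC was not tested. The make-up of DC differed as well, with cells of the Ccr7 cluster at 21.5% of DC in Sham, 32.5% in BT and 34.2% in ICI.

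The type I interferon list was higher in BT than in Sham and in each irradiated ICI library than in ICI. Free RNA from macrophages read in CD8 T cells was argued against, since the share of the macrophage difference seen in CD8 T cells was at least 65.4 times the share at which macrophage genes appear there. After correction for transcript length the smallest of 10 medians was 0.64, and outside the CD8 cluster with Ifit1 and Ifit3 the smallest of 5 was 0.34, which argues against length bias and against that cluster alone as the whole cause. A response to radiation is consistent with these values, but with 1 library per group a difference between animals, strains or handling stays open.

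Naive-type T and B cells were frequent in the ICI library alone. The excess over the next library was 8.30 times for the T cells and 5.79 times for the B cells. Lymph node tissue in the sample stays open, because its test rests on this same excess. Blood stays open, since hemoglobin was at 0.281 CPM of all UMIs in ICI, below the 0.362 of 8Gy+ICI and above the median of 0.111 of the other libraries. These values rest on 24 hemoglobin UMIs in ICI, 24 in Sham and 32 in 8Gy+ICI. Red cells had also been lysed and cells sorted for CD45, so hemoglobin cannot decide on blood. Checkpoint antibodies without radiation, at 8.20% naive-type T cells, cannot be told apart from the library itself, because no other library has that treatment.

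Nuclear genes of oxidative phosphorylation were higher in BT+ICI than in ICI and lower in 2Gy+ICI than in ICI, in CD8 T cells as in monocytes and macrophages. Transcript length correction left 8 of 8 medians at 0.5 or more of their value, and totals without mitochondrial and ribosomal protein genes also left 8 of 8, which argues against length bias and against these genes taking the counts. The medians did not rise with each radiation dose. For 2Gy+ICI against ICI the median was -0.46 in monocytes and macrophages. In CD8 T cells it was -0.30 (counting range -0.38 to -0.24), against 0.28 for 8Gy+ICI and 0.15 for 20Gy+ICI. These values cannot decide on a step with each dose, because the value of 2Gy+ICI is part of the pattern and each dose has 1 library. Whether other animals would show such a step stays open. UMIs per barcode were lowest in 2Gy+ICI and 8Gy+ICI (medians of 4096 and 4455), and the list was lower in 2Gy+ICI and higher in 8Gy+ICI than in ICI. No other biological explanation was tested.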
